A study of Mus musculus with 6 samples.

How the data were processed

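Total RNA from 6 pools of E13.5 mouse hearts, 3 control and 3 conditional knockout, was extracted with a Qiagen kit, amplified with the Ambion WT Expression kit and labelled with Affymetrix terminal labelling reagents, per the labels' protocols. The authors deposited log2 expression values made with RMA (robust multi-array average) in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, brings the arrays to a shared distribution of signal and summarises the probes of a transcript cluster to 1 log2 value. It therefore removes differences in total signal between arrays, and a change shared by most genes would not be visible. The software version, the annotation release and the probe set level are not given in the sources used here. Values per array ranged from 2.08 to 14.5 overall. No detection p-values were used here, so low values cannot be separated from background, and RMA compresses the fold changes of dim probe sets. The labels name biological replicates, and each array holds RNA of 4 to 6 hearts, so the spread between arrays is a spread between pools and not between single embryos.

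Groups were taken from the genotype labels. The controls lacked Cre, so the 2 genotypes differ in the presence of the Mesp1-Cre allele as well as in Hic2. The labels give no batch, litter or sex. No pair of arrays held duplicated data, with 2 to 10 identical values among 23332 rows per pair.

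Rows were named through the platform's annotation table. Of the 23332 rows, 14996 carried exactly 1 gene symbol, 1019 carried several and were not used for naming, and 7317 were unnamed here. Of the single-symbol rows, 14941 gene identifiers were found in a mouse reference gene table (assembly GRCm38.p6), and 0 symbols changed. That table was used only for names and for which genes lie near Mesp1, and no coordinates are given because the array annotation's genome build is not given in the sources used here. For 135 genes with more than 1 probe set, the probe set with the highest mean was kept and 136 were set aside. This left 14860 genes, with no filter on dim probe sets.

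Genes were compared with limma 3.58.1 (lmFit and eBayes with the default prior) in R 4.3.3, as conditional knockout minus control, two-sided, on the deposited log2 values without further normalisation. The Benjamini-Hochberg adjusted p had to be under 0.05. The moderated test had 7.46 degrees of freedom, and the median standard error of a log2 fold change was 0.08. Errors printed with log2 changes are standard errors from this fit, and those printed with levels are SDs over 3 arrays. Hic2 was also compared by an exact two-sided permutation test of the group means.

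The text names Hic2, then up to 15 genes in each direction with the largest absolute log2 change among those past the threshold whose groups did not overlap. For each gene list it names the members past the threshold over all genes or over the list alone, and otherwise up to 4 members with the smallest unadjusted p. The adjustment over the list alone ran within each list, with no correction across lists. It is the weaker criterion, as 2607 of the 14860 genes had an unadjusted p under 0.05. A member that passed it alone did not pass over all genes. Predicted genes, olfactory receptors, small RNAs and near-identical families were not named by the rule on single genes, which left out 1 gene past the threshold, Rpl4, named only as a list member.

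Gene lists, the rule for naming, the test designs and most alternative settings were chosen before the data were examined. The 34 lists cover cell types of the heart, chambers, heart transcription factors, signalling pathways, energy metabolism, stress, proliferation, the orthologues of human 22q11.2 genes, genes reported as HIC1 or HIC2 targets, other tissues a dissection could carry along, blood cells and sex-linked genes. Of 632 listed entries 508 were measured. Lists with at least 3 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 33 lists, and beside it with a correlation estimated per list and with fry. Camera asks whether a list's genes move more than other genes do. Fry asks whether they move on balance in 1 direction and makes no comparison with other genes.

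The tests were tried on simulated data made from the real means. Of 100 genes changed 1.5-fold, 92 were recovered, and of 100 changed 2-fold, 99 were recovered, with 14 false calls among 14860 genes. The list test called the 1 list that was raised and 0 others of the 33. The simulated genes were drawn independently of each other, with normal noise of the moderated SD from the real fit. The recovered and false counts therefore need not hold for the real arrays. The simulation also cannot show how often the list test makes false calls where genes are correlated. Alternatives were the replicate number as a block, a variance trend with robust moderation, array weights, median centring, quantile normalisation, only genes with a mean above the median gene, the mean of a gene's probe sets, every row of the table, other thresholds, other list tests and leaving out each array in turn. A covariate for sex and lists without single members were added after seeing the data.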

Results

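Gene expression was measured in mouse hearts dissected at E13.5, an embryonic stage in mid-gestation. The design addresses removal of Hic2, which codes for a zinc finger transcription factor, in the developing heart. It held no group with Cre alone, so it cannot separate Hic2 removal from the Cre allele. Control embryos carried 2 floxed copies of Hic2 and no Cre. Conditional knockout embryos carried the same floxed alleles with 1 copy of Mesp1-Cre, a recombinase expressed in the early mesoderm that gives rise to most of the heart. Each genotype had 3 biological replicates, and each replicate was a pool of 4 to 6 hearts hybridised to 1 Affymetrix mouse exon array. The deposited values were log2 expression values whose medians per array lay between 7.41 and 7.48. The 6 arrays correlated with each other at 0.993 to 0.997 across the 14860 genes tested. With 3 arrays per genotype, the number of arrays limits the precision of every value. Of the sex-linked genes fixed in advance, only Eif2s3y and Kdm5d, both on the Y chromosome, were measured, and a list with under 3 measured members was not tested. Eif2s3y stood at 4.36 in control replicate 3 and at 8.51 to 9.64 in the other 5 arrays. Kdm5d stood at 5.33 in control replicate 3 and at 7.15 to 8.23 elsewhere.

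Hic2 signal was slightly lower in the knockout and did not pass the test. The Hic2 probe set (identifier 6839733) had a log2 value of 8.17 ± 0.08 (SD, n = 3) in control hearts and 8.02 ± 0.06 (SD, n = 3) in conditional knockout hearts. The difference was -0.14 on the log2 scale (95% confidence interval -0.30 to 0.01), which is a signal 9.55% lower in the knockout. All 3 knockout arrays lay below all 3 control arrays, and an exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 arrays allow. In the limma fit across all genes the adjusted p was 0.314, which is short of the threshold. The positions of this probe set's probes relative to the floxed part of Hic2 are not given in the sources used here, and probes outside the deleted part would check nothing about the genotype labels.

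Among 14860 genes, 83 differed between conditional knockout and control hearts at a limma adjusted p under 0.05, with 50 higher and 33 lower in the knockout. The largest increase was in Tnnt3, the fast skeletal muscle form of troponin T, which rose by 1.81 ± 0.14 on the log2 scale (SE), or 3.52-fold, from 8.42 ± 0.21 to 10.23 ± 0.22 (SD, n = 3 each). The metallothioneins Mt2 and Mt1, small metal-binding proteins, rose by 1.34 ± 0.10 and 0.84 ± 0.07. Uts2b, which codes for a vasoactive peptide, rose by 1.19 ± 0.08. Egln3, an oxygen-sensing prolyl hydroxylase, rose by 1.15 ± 0.12, and Aldoc, a glycolytic aldolase, rose by 0.78 ± 0.06. Nppb, the gene for brain natriuretic peptide, rose by 0.93 ± 0.13 from 11.25 ± 0.23 to 12.18 ± 0.16 (SD, n = 3 each). The potassium channel subunit Kcne3 rose by 1.11 and the mitochondrial protein gene Mgarp by 1.06. Further increases were in the immediate early gene Ier3 (0.97), the protease inhibitor A2m (0.96), the Fc receptor Fcgr4 (0.94), the inflammatory caspase Casp4 (0.92), the cytokine Tnfsf9 (0.90) and the scavenger receptor Msr1 (0.87).

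Several of the largest decreases were in genes with known roles in red blood cells. Trim10, a gene of erythroid differentiation, fell by 1.33 ± 0.11 on the log2 scale (SE), from 8.86 ± 0.16 to 7.53 ± 0.17 (SD, n = 3 each). Slc4a1, the anion exchanger of the red cell membrane, fell by 1.32 ± 0.12, and the membrane skeleton gene Epb42 fell by 1.13 ± 0.11. Alas2, the erythroid enzyme that begins haem synthesis, fell by 0.90 ± 0.08 from 12.55 ± 0.09 to 11.64 ± 0.11 (SD, n = 3 each). Kel, a blood group antigen, fell by 1.06, the mitochondrial iron importer Slc25a37 by 1.01, the carbonic anhydrase Car2 by 0.93 and the blood group gene Rhd by 0.73. Fech, which inserts iron into haem, fell by 0.64, and Bpgm, which makes the red cell's regulator of oxygen release, fell by 0.66. The other named decreases were in Pdzk1ip1 (-0.74), the ubiquitin-conjugating enzyme Ube2o (-0.71), the slow skeletal muscle gene Mybpc1 (-0.70), the adaptor Grap2 (-0.67) and Nxpe2 (-0.62).

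Of the 83 genes, 12 changed at least 2-fold (7 higher, 5 lower) and 50 at least 1.5-fold. The smallest adjusted p was 0.00883, shared by Tnnt3, Mt2, Uts2b, Aldoc, Mt1, Trim10 and Alas2 among the genes named. In each of the 83 genes the 3 knockout values lay all above or all below the 3 control values. Such separation occurred in 24.6% of all genes tested, against 10% by chance. At an unadjusted p under 0.05, 2607 genes differed (1597 higher, 1010 lower), where 743 would be reached by chance. The count of 83 fell to 11, 3 and 13 without control replicates 1, 2 and 3, and to 26, 28 and 14 without knockout replicates 1, 2 and 3, and of the genes named above only Tnnt3, Mt2 and Uts2b passed in all 6 of these refits. Testing every row of the array, unnamed probe sets included, left 0 genes past the limma threshold with 2935 rows at an unadjusted p under 0.05, while weighting arrays by quality gave 733 genes and keeping only the brighter probe sets gave 443.

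**Figure D1:**
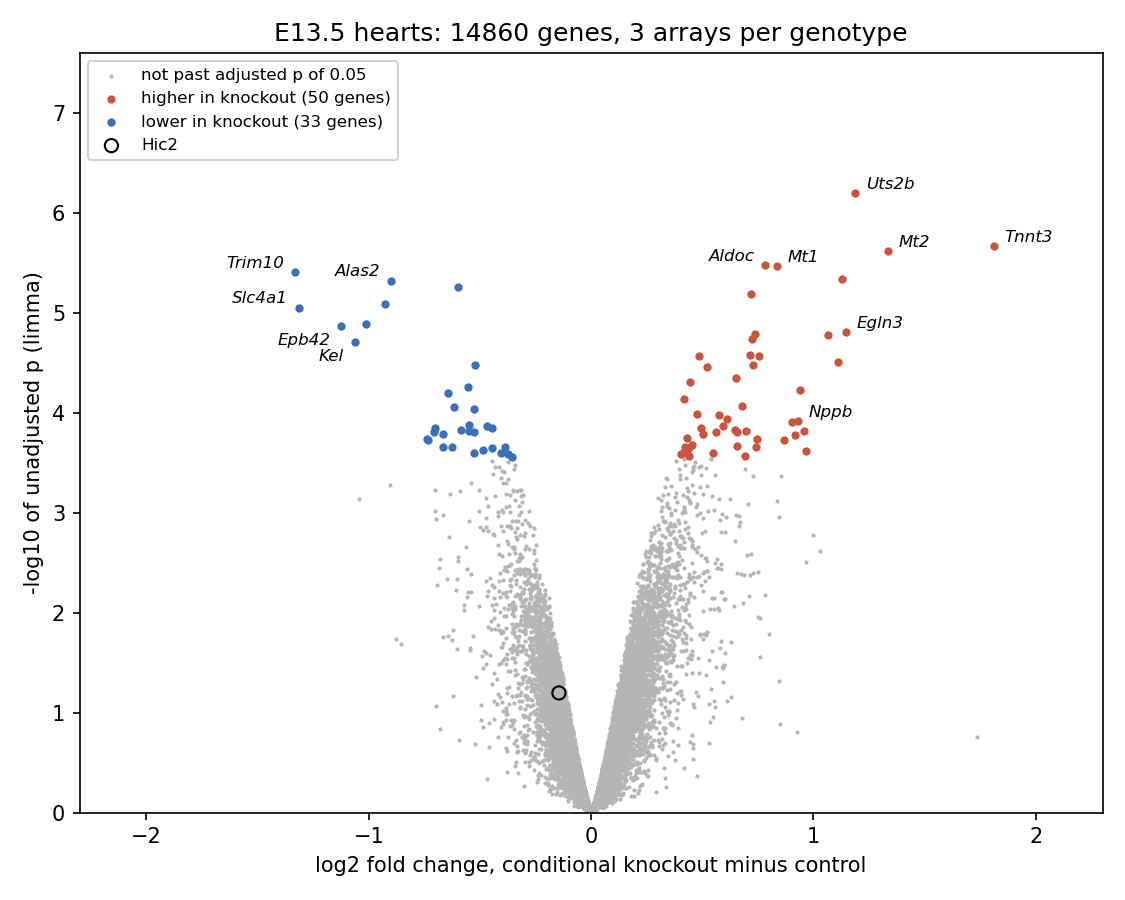
Each point is 1 of 14860 genes, with the log2 fold change (conditional knockout minus control) on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis. The 50 higher genes (orange) reach a log2 change of 1.81 at Tnnt3, the 33 lower genes (blue) reach -1.33 at Trim10, and Hic2 (open circle) lies among the genes not past an adjusted p of 0.05 (grey).

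Of 34 gene lists fixed before the data were examined, 33 had enough measured members to be tested, and 11 passed limma's camera test, 8 higher and 3 lower in the knockout. All 11 calls rest on a preset correlation between genes of 0.01. With a correlation estimated per list, 0 lists passed, the smallest adjusted p being 0.355, although 8 lists passed limma's fry test, 7 of them among the 11. The value with an estimated correlation is given beside each call. With the preset correlation, divisions of the arrays that mixed the genotypes also gave small unadjusted camera p values. The smallest were 3.28e-07 for hypoxia genes (1.04e-11 in the real division), 4.49e-06 for erythroid genes (9.08e-14) and 2.41e-05 for macrophage genes (1.08e-07). They were 9.56e-05 for fatty acid oxidation genes (3.57e-05) and 3.70e-12 for megakaryocyte genes (0.00925). A small camera p alone therefore does not mark a genotype difference.

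Erythroid genes had the lowest median of the 33 lists. Of 13 measured members all 13 were lower in the knockout, with a median log2 change of -0.73 (camera adjusted p = 3.00e-12, and adjusted p = 0.355 with an estimated correlation). By single-gene tests 5 members were lower over all genes and 9 were lower when adjusted over the list alone. Besides Trim10, Slc4a1, Epb42, Alas2 and Rhd, these were the Rh-associated glycoprotein Rhag (-1.04 ± 0.19, SE), the blood group gene Ermap (-0.90 ± 0.16), Tspan33 (-0.33 ± 0.06) and the embryonic alpha-like globin Hba-x (-0.26 ± 0.09). The embryonic beta-like globin Hbb-y, at 14.44 ± 0.06 in control and 14.33 ± 0.03 in knockout hearts (SD, n = 3), lay near the top of the array's range, whose highest value was 14.5, and did not pass. The erythroid transcription factors Gata1 (-0.23) and Klf1 (-0.05) did not pass either. No member of this list was in another list. Leaving out both globins, a choice made after seeing the data, gave a camera adjusted p of 8.43e-12. Both globins changed less than the list median, which was -0.90 without them, so leaving them out could hardly lose the call.

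Platelet and megakaryocyte genes were lower as a group but no single member passed. The 6 measured members had a median of -0.27 (camera adjusted p = 0.0309, and adjusted p = 0.754 with an estimated correlation), with 0 past the threshold over all genes and 0 adjusted over the list alone. The members with the smallest p were the chemokine Ppbp (-0.35 ± 0.13, SE), the integrin Itga2b (-0.38 ± 0.15), Treml1 (-0.22 ± 0.09) and the von Willebrand receptor subunit Gp9 (-0.32 ± 0.14). The list did not pass without control replicate 1 (adjusted p = 0.169), control replicate 2 (0.0893), knockout replicate 1 (0.0966) or knockout replicate 3 (0.111), and its median was -0.45 without control replicate 3. In 3 of the 10 ways of dividing the 6 arrays into groups of 3, the real one included, its unadjusted p was as small as in the real division.

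Hypoxia response and glycolysis genes rose as a group in the knockout. Of 21 measured members 20 were higher, with a median log2 change of 0.40, or 1.32-fold (camera adjusted p = 1.72e-10, and adjusted p = 0.355 with an estimated correlation). Over all genes 3 members were higher, Egln3, Aldoc and the carbonic anhydrase Car9 (0.61 ± 0.08, SE), and 14 were higher when adjusted over the list alone. Those 14 included the vasodilator peptide Adm (1.00 ± 0.21), Ndrg1 (0.83 ± 0.15), the mitophagy receptor Bnip3 (0.48 ± 0.09), the angiogenic growth factor Vegfa (0.46 ± 0.11), Ankrd37 (0.45 ± 0.10) and the glycolytic regulator Pfkfb3 (0.43 ± 0.14). The collagen prolyl hydroxylases P4ha1 (0.41) and P4ha2 (0.40), hexokinase Hk2 (0.35), phosphofructokinase Pfkl (0.18) and the pyruvate dehydrogenase kinase Pdk1 (0.17) completed them. The glucose transporters Slc2a1 (-0.08 ± 0.12) and Slc2a3 (0.20 ± 0.23) did not pass. Without knockout replicate 1 the list's median fell from 0.40 to 0.27. The lower erythroid signal (median -0.73) and the higher macrophage signal (median 0.17) occurred in the same knockout arrays.

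Macrophage and leukocyte genes were higher in the knockout. All 17 measured members were higher, with a median of 0.17 (camera adjusted p = 1.19e-06, and adjusted p = 0.355 with an estimated correlation). Over all genes 2 members were higher, the complement gene C1qc (0.45 ± 0.07, SE) and the Fc receptor Fcgr3 (0.69 ± 0.11), and 7 were higher when adjusted over the list alone. The other 5 were C1qa (0.52 ± 0.08), C1qb (0.49 ± 0.09), the lysosomal marker Cd68 (0.39 ± 0.08), and the Fc receptor signalling genes Tyrobp (0.34 ± 0.11) and Fcer1g (0.23 ± 0.08). C1qa, for example, stood at 7.97 ± 0.07 in control and 8.48 ± 0.14 in knockout hearts (SD, n = 3). No member was shared with another list, and the median was 0.27 without control replicate 2.

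**Figure D2:**
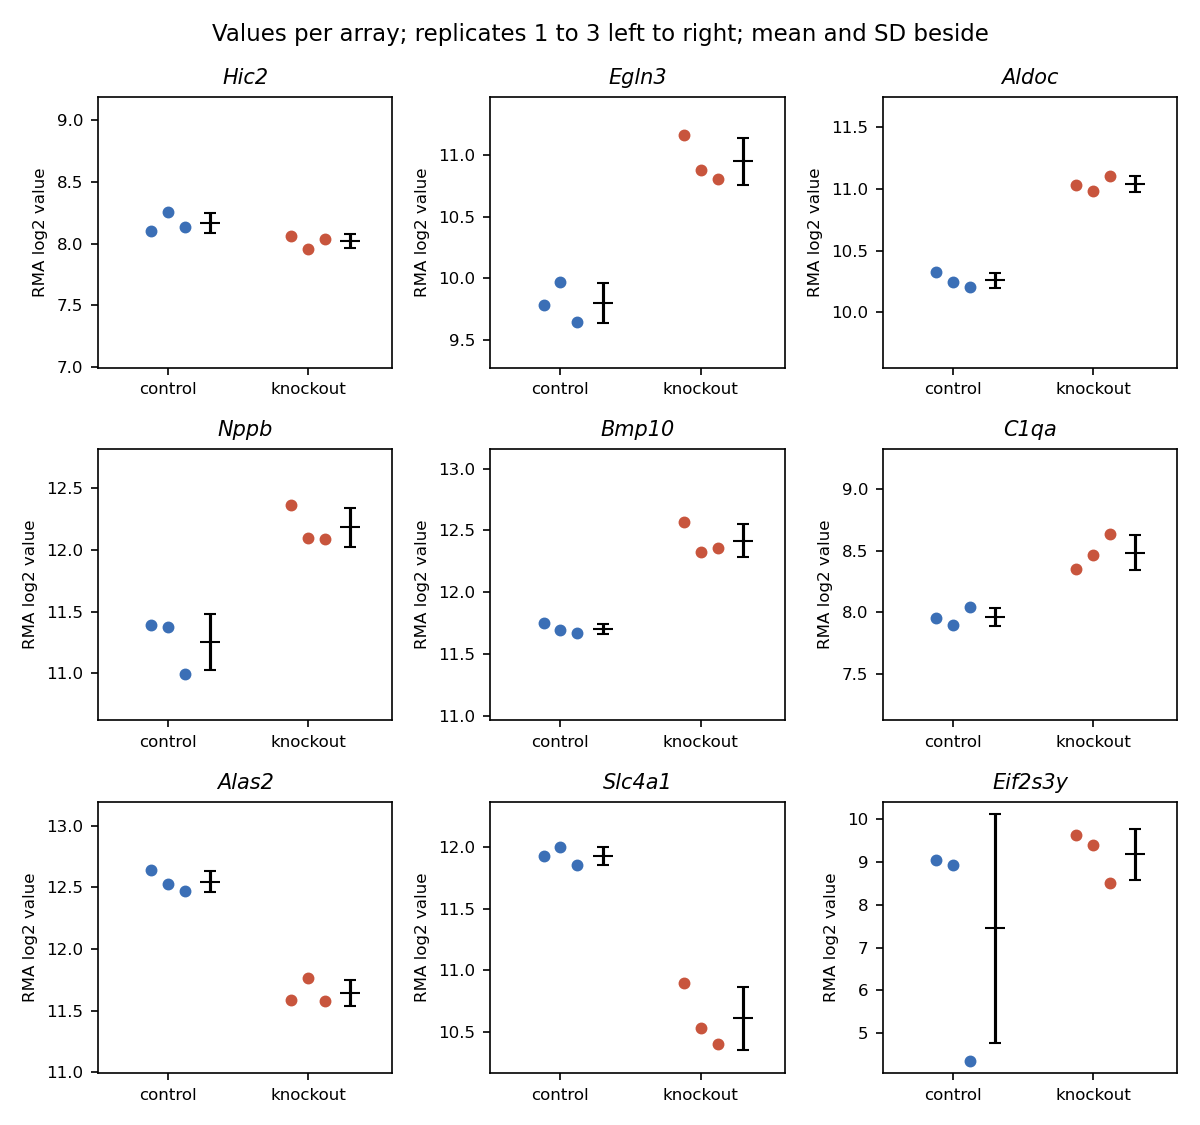
Each point is the log2 value of 1 array for Hic2, Egln3, Aldoc, Nppb, Bmp10, C1qa, Alas2, Slc4a1 and Eif2s3y, with control in blue, conditional knockout in orange, and the mean and SD of 3 arrays beside them; the vertical axes have equal span but different positions, apart from Eif2s3y, whose span is wider. Egln3, Aldoc, Nppb, Bmp10 and C1qa were higher and Alas2 and Slc4a1 lower in all 3 knockout arrays, and Eif2s3y was at 4.36 in control replicate 3.

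Epicardial genes were mostly higher. Of 13 measured members 11 were higher, with a median of 0.20 (camera adjusted p = 9.16e-05, and adjusted p = 0.443 with an estimated correlation). Over all genes 3 were higher, the retinoic acid synthesising enzyme Aldh1a1 (0.75 ± 0.08, SE), mesothelin Msln (0.57 ± 0.08) and the uroplakin Upk1b (0.41 ± 0.06). There were 7 higher when adjusted over the list alone, adding Krt19 (0.52 ± 0.13), the transcription factor Wt1 (0.28 ± 0.06), Podxl (0.20 ± 0.07) and Lrrn4 (0.19 ± 0.07), and 1 was lower, the transcription factor Tbx18 (-0.24 ± 0.08). Over all genes the limma adjusted p of these added members and Tbx18 lay between 0.106 (Wt1) and 0.215 (Podxl).

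Vascular and connective tissue lists did not pass as groups. The 20 endothelial and endocardial genes had a median of 0.07 (camera adjusted p = 0.229), with 0 past the threshold over all genes. Adjusted over the list alone, Icam2 (0.45 ± 0.07, SE), Emcn (0.35 ± 0.06), Egfl7 (0.27 ± 0.07) and Ramp2 (0.24 ± 0.07) were higher and the transcription factor Sox17 (-0.27 ± 0.07) was lower. Without knockout replicate 3 this list passed with an adjusted p of 0.0491. Among 14 smooth muscle and pericyte genes the median was -0.06 (adjusted p = 0.229), and 1 member, the potassium channel gene Kcnj8, fell by 0.53 ± 0.08, both over all genes and adjusted over the list alone. Without knockout replicate 1 this list passed with an adjusted p of 0.0458. The 18 endocardial cushion and valve mesenchyme genes had a median of -0.05 (adjusted p = 0.413) with 0 past either threshold, Prrx2 (-0.21 ± 0.09), Sox9 (-0.18 ± 0.08), Scx (0.33 ± 0.16) and Msx2 (0.24 ± 0.18) having the smallest p. That list passed without control replicate 3 (adjusted p = 0.0263) and with array weights (0.0233). The 19 collagen, matrix and fibroblast genes had a median of -0.03 (adjusted p = 0.291) with 0 past either threshold, Ogn (0.31 ± 0.08), Pdgfra (-0.35 ± 0.12), Col5a1 (-0.22 ± 0.08) and Col3a1 (-0.24 ± 0.08) having the smallest p.

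Ventricular trabecular genes moved in both directions. Over all genes Nppb and Bmp10, a growth factor of trabecular myocardium, were higher, Bmp10 by 0.71 ± 0.08 (SE) from 11.70 ± 0.04 to 12.42 ± 0.13 (SD, n = 3 each). Of the 10 members 5 were higher when adjusted over the list alone, adding Irx3 (0.28 ± 0.07), Cited1 (0.26 ± 0.08) and the atrial natriuretic peptide gene Nppa (0.25 ± 0.06). In the same adjustment 2 were lower, Cpne5 (-0.47 ± 0.09) and the neuregulin co-receptor Erbb2 (-0.24 ± 0.06). The list had a median of 0.21 and missed the threshold (camera adjusted p = 0.0689), but passed without control replicate 3 (0.0488), without knockout replicate 3 (0.0480) and with fry (0.0314).

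Contractile and chamber genes did not pass as groups. The 18 cardiomyocyte contractile and identity genes had a median of 0.01 (camera adjusted p = 0.838) with 0 past the threshold over all genes and 0 adjusted over the list alone. Myom2 (0.75 ± 0.22, SE), Mybpc3 (-0.16 ± 0.06), Des (-0.14 ± 0.06) and Nebl (-0.14 ± 0.07) had the smallest p. The median and mean of this list were above 0 while the test pointed down, and the median turned below 0 after median centring or quantile normalisation. In the 10 compact layer genes (median 0.03, adjusted p = 0.697) the potassium channel subunit Kcne1 (0.54 ± 0.08) was higher adjusted over the list alone and 0 passed over all genes; this median turned below 0 after quantile normalisation. In the 14 atrial chamber genes (median -0.01, adjusted p = 0.697) 0 passed over all genes, and adjusted over the list alone Nppa was higher and the transcription factor Nr2f1 (-0.50 ± 0.09) was lower.

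Transcription factors of the heart moved both ways. Of the 22 cardiac transcription factors (median -0.05, camera adjusted p = 0.916) 0 passed over all genes. Adjusted over the list alone the Iroquois factors Irx6 (0.71 ± 0.19, SE), Irx5 (0.42 ± 0.07) and Irx3 were higher and Nkx2-5 (-0.37 ± 0.10) was lower, Nkx2-5 standing at 12.16 ± 0.03 in control and 11.79 ± 0.21 in knockout hearts (SD, n = 3). The mean of this list lay above 0 while its median and test lay below. The 19 calcium handling, ion channel and conduction genes had a median of -0.07 (adjusted p = 0.257), and the 15 second heart field and outflow tract genes a median of -0.04 (adjusted p = 0.338), with 0 members past either threshold. The smallest p in the former belonged to Shox2 (-0.24 ± 0.07), Kcnh2 (-0.13 ± 0.06), Casq2 (0.23 ± 0.10) and Atp2a2 (-0.15 ± 0.07). In the latter it belonged to Wnt5a (-0.23 ± 0.07), Foxc2 (0.18 ± 0.09), Rspo3 (-0.24 ± 0.12) and Tbx1 (-0.11 ± 0.08).

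**Figure D3:**
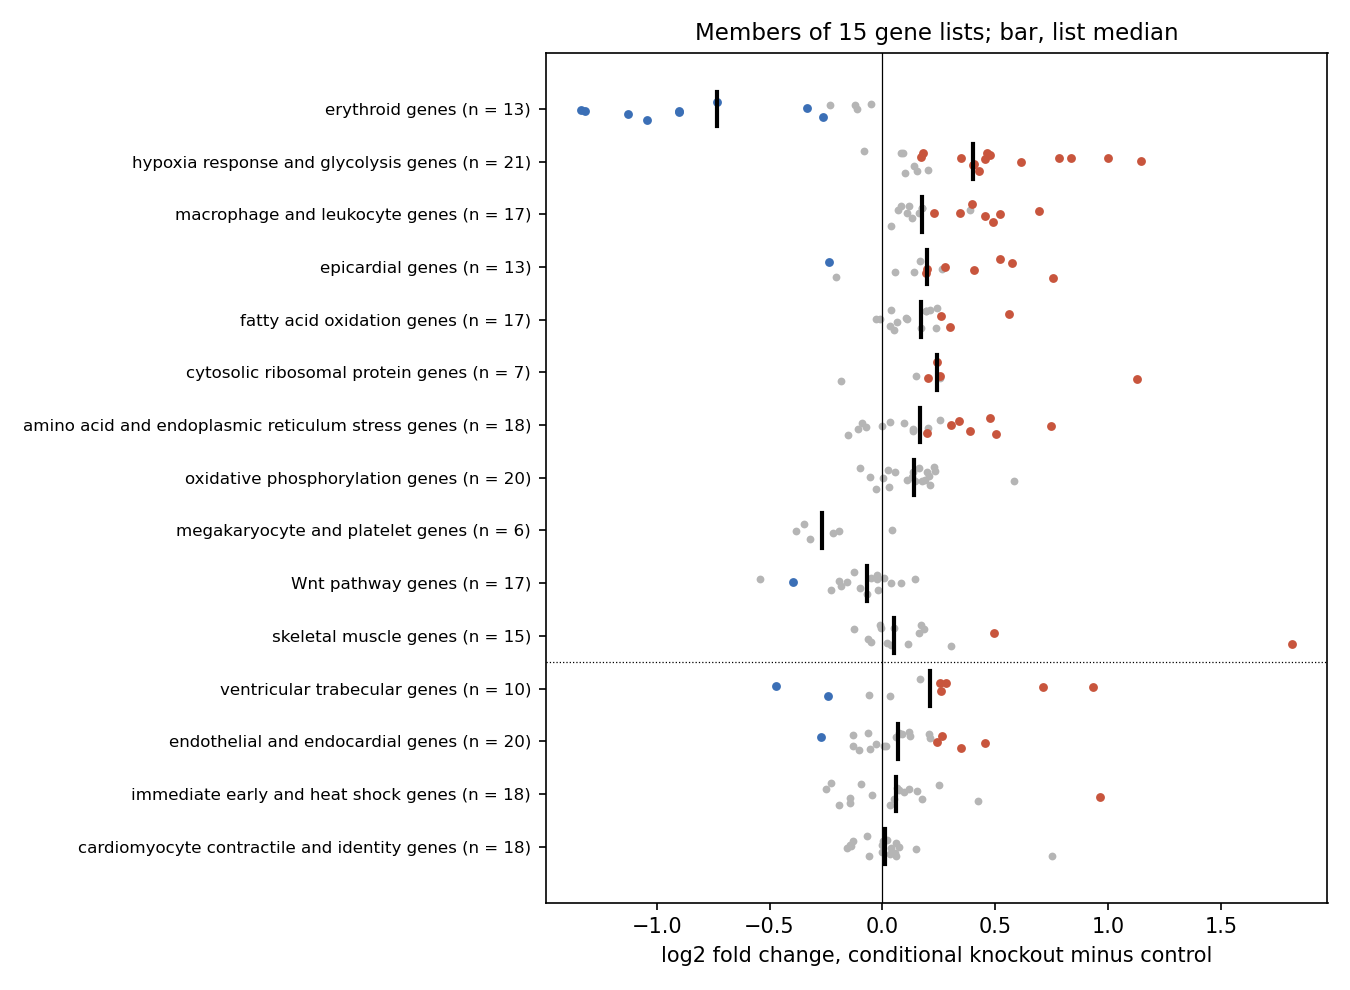
Each point is the log2 fold change (conditional knockout minus control) of 1 measured member of 15 gene lists, orange or blue where it passed when adjusted over the list alone (higher or lower) and grey otherwise, with a black bar at the list median. The 11 lists above the dotted line passed the camera test with the preset correlation, from a median of -0.73 for erythroid genes to 0.40 for hypoxia response and glycolysis genes, and the 4 below it did not.

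Genes of fuel use and energy production were slightly higher as groups. The 17 fatty acid oxidation genes had a median of 0.17 (camera adjusted p = 0.000235, and adjusted p = 0.366 with an estimated correlation), with 15 higher, 0 past the threshold over all genes and 3 adjusted over the list alone. Those 3 were the lipid-sensing receptor Ppara (0.56 ± 0.09, SE), the pyruvate dehydrogenase kinase Pdk4 (0.30 ± 0.07) and the carnitine acyltransferase Cpt2 (0.26 ± 0.06). The 20 oxidative phosphorylation genes had a median of 0.14 (adjusted p = 0.00361, and adjusted p = 0.606 with an estimated correlation), with 17 higher and 0 past either threshold. Cox8b (0.58 ± 0.14) and the succinate dehydrogenase subunits Sdhd (0.23 ± 0.07), Sdhc (0.20 ± 0.06) and Sdhb (0.21 ± 0.07) had the smallest p. In 3 of the 10 ways of dividing the arrays, the real one included, this list's unadjusted p was as small as in the real division.

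Of 28 cytosolic ribosomal protein genes 7 had a probe set of their own name, and these were higher as a group, with a median of 0.24 (camera adjusted p = 0.00101, and adjusted p = 0.355 with an estimated correlation). Over all genes 1 passed, Rpl4 (1.13 ± 0.10, SE), and 4 were higher when adjusted over the list alone, adding Rpl22 (0.25 ± 0.06), Rpl8 (0.24 ± 0.07) and Rps3 (0.20 ± 0.06). The Rpl4 probe set was dim, at 5.03 ± 0.14 in control and 6.16 ± 0.14 in knockout hearts (SD, n = 3). Its control level lay below the lower quartile of every array (5.31 to 5.37). Ribosomal protein genes have many near-identical pseudogenes, so these values are uncertain. Without Rpl4, Rplp0 and Rps18, a choice made after seeing the data, the adjusted p was 0.00424.

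Amino acid and endoplasmic reticulum stress genes rose as a group. Of 18 measured members 14 were higher, with a median of 0.17 (camera adjusted p = 0.00135, and adjusted p = 0.355 with an estimated correlation). Over all genes 2 were higher, the glutathione-degrading enzyme Chac1 (0.75 ± 0.11, SE) and the mitochondrial folate enzyme Mthfd2 (0.50 ± 0.07), and 7 adjusted over the list alone. The other 5 were asparagine synthetase Asns (0.48 ± 0.09), the transcription factor Ddit3 (0.39 ± 0.09), the lipoprotein receptor Vldlr (0.34 ± 0.08), the cystine transporter Slc7a11 (0.30 ± 0.06) and the serine to glycine enzyme Shmt2 (0.20 ± 0.06).

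Other stress and cell cycle lists did not pass. Among 18 immediate early and heat shock genes (median 0.06, camera adjusted p = 0.697) only Ier3 was higher, both over all genes and adjusted over the list alone. Among 14 p53 response genes (adjusted p = 0.697) only the cell cycle inhibitor Cdkn1a (0.55 ± 0.08, SE) was higher in both adjustments, and the median of -0.01 lay below 0 while the mean and test lay above. Of 10 interferon response genes (median 0.01, adjusted p = 0.922) the antiviral gene Rsad2 (-0.55 ± 0.07) was lower over all genes. Adjusted over the list alone, Rtp4 (0.58 ± 0.15) and Bst2 (0.47 ± 0.12) were higher and Rsad2 was lower; the median of this list turned below 0 after median centring. The 23 proliferation genes had a median of -0.03 (adjusted p = 0.412) with 0 past either threshold, Mcm2 (-0.18 ± 0.05), Mcm5 (-0.22 ± 0.07), Ccne2 (0.23 ± 0.08) and Cdk1 (0.17 ± 0.06) having the smallest p.

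Signalling lists gave a small decrease of Wnt genes. The 17 Wnt pathway genes had a median of -0.07 (camera adjusted p = 0.0309, and adjusted p = 0.366 with an estimated correlation), with 13 lower, 0 past the threshold over all genes and 1, the ligand Wnt2 (-0.40 ± 0.07, SE), adjusted over the list alone. This list did not pass without control replicate 1 (adjusted p = 0.0909) or knockout replicate 2 (0.0629), and its median was -0.11 without control replicate 2 or 3. The 19 BMP and TGF-beta pathway genes had a median of 0.11 (adjusted p = 0.229), with Bmp10 higher over all genes. Adjusted over the list alone Bmp10, the BMP target genes Id1 (0.32 ± 0.10) and Id3 (0.29 ± 0.09), and Tgfb1 (0.29 ± 0.06) were higher and Bmp5 (-0.34 ± 0.08) was lower. The 15 Notch pathway genes (adjusted p = 0.814) had 0 past either threshold, Dll4 (0.19 ± 0.05), Jag1 (-0.31 ± 0.11), Dll1 (-0.19 ± 0.07) and Hey2 (0.10 ± 0.06) having the smallest p. The Notch median of 0.01 lay above 0 while the mean and test lay below, and it turned below 0 after median centring or quantile normalisation.

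Genes reported elsewhere as targets of HIC1 or HIC2 did not pass as a group. The 13 measured members had a median of 0.00 (camera adjusted p = 0.887), and this median turned below 0 after median centring or quantile normalisation. Cdkn1a was higher over all genes. When adjusted over the list alone, Cdkn1a, the ephrin Efna1 (0.35 ± 0.08, SE) and Tgfb1 were higher and Mtss1 (-0.28 ± 0.08) was lower. The 37 measured orthologues of human 22q11.2 genes had a median of -0.03 (adjusted p = 0.296) with 0 past the threshold over all genes and 0 adjusted over the list alone. Dgcr8 (-0.26 ± 0.06), Hira (-0.26 ± 0.07), Slc25a1 (0.25 ± 0.09) and Sdf2l1 (0.25 ± 0.10) had the smallest p.

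Of the lists for tissues outside the heart, skeletal muscle alone passed. The 15 skeletal muscle genes had a median of 0.05 (camera adjusted p = 0.0473, and adjusted p = 0.754 with an estimated correlation), with Tnnt3 higher over all genes and Tnnt3 and creatine kinase Ckm (0.49 ± 0.11, SE) adjusted over the list alone. Without Tnnt3, a choice made after seeing the data, the adjusted p was 0.229. With all members it was 0.0506, 0.0574 and 0.0662 without control replicates 1, 2 and 3, where the median was 0.09, 0.06 and 0.02, and 0.163 and 0.108 without knockout replicates 2 and 3, where it was 0.09 and 0.04. Without knockout replicate 1 the median was 0.12. As many as 3 of the 10 divisions of the arrays gave an unadjusted p as small as the real one. Among 12 liver genes (adjusted p = 0.291) 0 passed over all genes and 4 were higher adjusted over the list alone, Rbp4 (0.47 ± 0.10), Trf (0.45 ± 0.08), Ahsg (0.38 ± 0.11) and Ttr (0.23 ± 0.06), with the median of -0.03 below 0 and the mean and test above. Among 15 lung, airway and gut epithelial genes (median -0.11, adjusted p = 0.351) 0 passed over all genes and Etv5 (0.42 ± 0.09) was higher adjusted over the list alone. The 16 neural crest, glial and neuronal genes had a median of -0.02 (adjusted p = 0.636) with 0 past either threshold, Nefm (-0.17 ± 0.06), Elavl4 (0.17 ± 0.07), Dbh (0.13 ± 0.06) and Nefl (-0.22 ± 0.13) having the smallest p.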

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

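The covariate for sex and the lists without single members were chosen after seeing the data. The sign of the log2 change was kept by all 83 genes in every refit that tested them, and by the other 79 list members named in 1087 of 1087 values. Since the groups of all 83 did not overlap, leaving out or weighting arrays could not have reversed their signs. The 79 were chosen because they passed over their list in these same data, so kept signs say little. The count of 83 genes became 203 with a variance trend and robust moderation and 733 with array weights, which gave knockout replicate 2 a weight of 4.19 and the others 0.556 to 1.78; all 83 were among both. It became 443 among the 7431 brighter genes, 50 with a fold of at least 1.5 added, 287 at an adjusted p under 0.1, and 0 when all 23332 rows were tested (limma, 2935 at an unadjusted p under 0.05, smallest adjusted p 0.0849). In that last fit the prior degrees of freedom were 1.99 against 3.46, and more rows were adjusted for. A covariate for sex gave 11 genes. Leaving out 1 array gave 3 to 28 genes, with fewer arrays in each fit. The cause of the other shifts was not tested. Median centring (86), quantile normalisation (91) and the mean of a gene's probe sets (83) stayed within 1.5 times the count. The excess of higher over lower genes shrank with the first 2 of these. Median centring gave 45 higher and 41 lower genes, with 67 of the 83 among them. Quantile normalisation gave 49 higher and 42 lower, with 73 of the 83 among them.

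The replicate numbers did not pair the arrays: the deviations of same-numbered arrays correlated at -0.04, 0.02 and 0.13, and 2 of 6 arrays correlated best with their own number. With the replicate number as a block, 38 genes passed, 31 of them among the 83.

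Hic2 stayed lower and short of the threshold under every alternative, at -0.18 to -0.10 with 1 array left out. The count of 11 lists fell to 0 with a correlation estimated per list and was 8 to 12 with 1 array left out. Erythroid, hypoxia, macrophage, epicardial, fatty acid oxidation, ribosomal and amino acid stress lists kept their calls in 15 of the 16 settings chosen in advance, the exception being the estimated correlation. Oxidative phosphorylation genes lost theirs with fry as well (adjusted p = 0.125). Skeletal muscle and Wnt genes also lost theirs with fry (0.152 and 0.125) and on ranks (0.139 and 0.0551), skeletal muscle genes with the sex covariate (0.0510), and megakaryocyte genes with fry (0.474) and array weights (0.0842). Trabecular genes gained a call with the block (0.0463), the variance trend (0.0445) and median centring (0.0402), and cushion genes with the sex covariate (0.0108). Lists short of the threshold changed the direction of their test in 21 cases. Signal over background was not measured here, so which dim genes were detectable is open.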

Other observations

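Of the 83 genes past the threshold, 60 were in no fixed list, and the following were chosen for mention after their values were seen. Those in this paragraph had limma adjusted p values between 0.0144 and 0.0471, and none of the genes was picked by a rule. The apelin receptor gene Aplnr fell by 0.55 ± 0.08 (SE) and the angiopoietin gene Angpt1 by 0.45 ± 0.07, while Tmem100, a target of BMP signalling in endothelium, rose by 0.74 ± 0.08 from 8.95 ± 0.01 to 9.69 ± 0.13 (SD, n = 3 each). The secreted Wnt inhibitor Sost rose by 0.49 ± 0.07 and the semaphorin Sema3b by 0.49 ± 0.05, and the activin subunit gene Inhba fell by 0.39 ± 0.06.

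Also chosen after their values were seen, the cationic amino acid transporter Slc7a3 rose by 0.72 ± 0.08, and the aromatic amino acid transporter Slc16a10 (-0.55 ± 0.08), the glycine transporter Slc6a9 (-0.53 ± 0.07) and the aquaporin Aqp9 (-0.37 ± 0.06) were lower. Their limma adjusted p values lay between 0.0149 and 0.0481. Of the carbonic anhydrase genes past the threshold, Car2 was at -0.93 and Car9 and Car8 were at 0.61 and 0.59.

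The tests on handling, on dilution, on red cell number, on called genes near Mesp1 and on sex as the whole cause, and the conditions under which other tests on sex, on Mesp1 and on handling decide nothing, were chosen only after the results they bear on had been seen. A sex difference between the groups as the whole cause of the count was argued against by 13 genes, all among the 83, that passed without control replicate 3, which lacked Y-linked signal, with Eif2s3y in the other controls (8.93 and 9.05) within the knockout range (8.51 to 9.64), though at an unadjusted p under 0.05 another split of those 5 arrays gave more genes (2380 against 2191), so chance stays open. For the other 70 genes sex makeup stays open, since the test fixed in advance was void: 100% of the 83 genes kept their sign and at least 50 percent of their change without that array (0.835 to 1.15 times) but also without any other array. With the sex covariate 10 of the 83 passed, the median absolute log2 change over all 83 going from 0.65 to 0.67 while the median SE went from 0.08 to 0.09 and the degrees of freedom from 7.46 to 6.56. Of the 83 genes, 1, Hddc3, lay within 10 Mb of Mesp1 (1.20%, exact 95% interval 0.0305 to 6.53), so most of the count came from genes elsewhere. The test of DNA of another strain beside the Mesp1-Cre allele asked for over 50 percent of the 83 there. Only 100 measured genes lay in that region, so this bound could hardly be reached and the test decides little. An effect of such DNA on genes elsewhere was not tested. For the region itself the explanation stays open, with 21% of 100 genes at an unadjusted p under 0.05 against 17.5% elsewhere (ratio 1.20, 95% interval 0.818 to 1.76, where the bound fixed in advance was 1.5). Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes, the real one with 83, and the highest other gave 0 in limma (with at most 1256 at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05, and an effect of Cre itself was not separated from an effect of Hic2 loss.

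Higher hypoxia response and glycolysis genes (median 0.40) may reflect a response of the knockout hearts, a hypothesis that the design cannot separate from an effect of Cre. Handling stress at dissection stays open. The median of the immediate early and heat shock genes was 0.058 (bootstrap 95% interval -0.09 to 0.14), below the hypoxia median as the test's bound asked. The bootstrap resampled the list's members and not the arrays, so its interval leaves out the spread between pools. Handling also need not move every member, 11 were higher and 7 lower, and Ier3 rose by 0.97. A smaller share of red cell RNA, which would raise all other transcripts alike, was not decided as a cause. Other genes of the same level had a median shift of 0.01, and 14 of the 21 hypoxia members, adjusted over the list, lay above it. Taking off a shift so near 0 repeats the single-gene result already seen, so the count of 14 is no separate evidence. An earlier test of the same explanation on 11 of those members, with the arrays as the spread, gave a difference of 0.38 (95% interval -0.04 to 0.79) and did not decide it. The real split of the arrays was the 1 split of 10 that gave as many lists, 11 against 10 in the highest other split, and 10 splits are too few for a share under 0.05.

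Lower erythroid genes may come from fewer red cells in the dissected hearts or from a change within red cells. These could not be told apart. Only 2 members, Alas2 and Slc4a1, had a mean log2 value between 10 and 13, where at least 3 were needed. Cochran's Q on the fit's standard errors (p = 0.00454) decides nothing, nor does an exact permutation test of Slc4a1 minus Alas2 (p = 0.2). That difference went from -0.62 in control to -1.03 in knockout hearts. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1. The globins Hba-x (13.94 in control, 13.68 in knockout) and Hbb-y (14.44 and 14.33) lay near the top of the array's range, and Gata1 (7.43 and 7.20) and Klf1 (7.09 and 7.04) lay outside the range tested.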
